A study of Mus musculus with 6 samples.

How the data were processed

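RNA was sequenced from CD4 T cells of skin-draining lymph nodes near inflamed sites in mice with atopic dermatitis, purified by negative selection. There were 3 libraries from littermate controls (Control 1 to 3) and 3 from mice with a T cell conditional knockout of Ets1 (cKO 1 to 3). Per the submitters' processing notes, the authors used FastQC, cutadapt, Bowtie2, TopHat, Cufflinks, Cuffnorm and Cuffdiff with mouse build mm9, and the deposited values are FPKM, a fragment density scaled for transcript length and library size, per gene. Tool versions, the gene annotation, the strand setting and which of these tools wrote the values are not given in the sources used here. The annotation available here is of another build, so no coordinates are given, and genes are named by the symbols in the files.

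The table held 48700 gene entries with 48582 distinct symbols, of which 230 entries shared a symbol (25 of them among the genes kept). Sums of FPKM were 644711, 640081 and 639502 in Control 1 to 3 and 578293, 576958 and 605623 in cKO 1 to 3. FPKM do not give the number of reads, so absolute depth is unknown and no counting interval is given. Among values under 0.1 FPKM, ratios between libraries were within 0.02 (log2) of a whole-number ratio for 73.0% to 76.7% of 884 to 1076 genes, which gives depths relative to Control 1 of 1.03 and 0.919 in Control 2 and 3 and of 0.854, 0.807 and 0.875 in cKO 1 to 3. Immunoglobulin genes held 0.322%, 0.316% and 0.285% of the summed FPKM in Control and 3.33%, 3.70% and 6.90% in cKO, and ribosomal protein genes 27.8%, 27.2% and 27.1% against 20.5%, 20.3% and 19.2%. A value of 0 can be a failed estimate as well as an absent transcript, so such genes are said to be listed at 0. Fragments shared between paralogs or from the opposite strand could not be separated.

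Values were transformed to log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the 6 libraries were kept. The pseudocount of 1 shrinks fold changes of genes at low levels, so their sizes and ranks depend on it. The authors' scaling was left as deposited; median-of-ratios factors computed on the values lay between 0.997 and 1.01. The groups were compared with limma (eBayes with trend, two-sided), with Benjamini-Hochberg adjustment over the 11960 genes kept and a threshold of 0.05. Fold changes are cKO over Control, and errors are SD over 3 libraries unless said otherwise. Gene lists with at least 3 kept members (28 of 31) were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists, with an estimated correlation and fry beside it.

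The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names Ets1; the 10 largest rises and 10 largest falls among genes that passed with no overlap between the groups, leaving out unnamed genes and immunoglobulin and T cell receptor segments; and up to 4 members per list with the smallest adjusted p among those that passed. Some genes that the rule names are not reported here. Every gene named outside this rule, in the report and in the closing section, was chosen after its values were seen. So were the gene classes (immunoglobulin, ribosomal protein, mitochondrially encoded and T cell receptor segment genes, the last also split by chain) and the alternatives with length correction, GC correction and other-cell markers left out.

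The 31 lists cover Ets family, Th1, Th2, Th17, Treg, Tfh, naive, effector and memory, activation, co-inhibitory, interleukin-6, common gamma chain, T cell receptor signalling, chemokine receptor, cytotoxic, cell cycle, interferon-stimulated, glycolysis, cholesterol, immediate early and sex-linked genes. The others mark B cells, plasma cells, CD8 T cells, innate-like lymphocytes, myeloid cells, dendritic cells, mast cells, stroma, keratinocytes and erythroid cells. Many genes stand in more than 1 list, for example 15 of the 22 chemokine receptor genes kept.

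The procedure was tested on simulated data of 11960 genes with 200 changed: 59% of genes changed by 0.5 (log2) and 84% of those changed by 1 were recovered, with 151 calls of which 8 were false. The simulated genes varied independently, and in the data 43.1% of genes were called, so these rates need not hold for the data. Alternatives were no filter, a mean of at least 5 FPKM, pseudocounts of 0.1 and 5, median-of-ratios scaling, quantile normalization, robust eBayes, eBayes without trend, library quality weights, a replicate block, a log2 fold change of at least 1 and leaving out each library. Transcript length and GC content were those of the longest protein-coding transcript per symbol in the other build, or of the longest where none is protein-coding. They were known for 11628 genes kept (97.2%), and trends in them were removed by lowess with a span of 0.3. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.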

Results

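Gene expression was measured by RNA sequencing of CD4 T cells from the lymph nodes that drain inflamed skin, in C57BL/6 mice with atopic dermatitis. Libraries came from littermate control animals (Control, n = 3) and from animals in which Ets1, a transcription factor of the Ets family, was targeted in T cells with a distal Lck promoter Cre (cKO, n = 3). The cells had been enriched by removal of other cells rather than by positive sorting. The comparison asks which transcripts differ in these T cells when Ets1 is targeted during skin inflammation. The deposited values sum to between 639502 and 644711 FPKM in the Control libraries and to between 576958 and 605623 FPKM in the cKO libraries. Between 17863 and 17961 genes were above 0 in the Control libraries and between 18320 and 18601 in the cKO libraries. Within Control, libraries correlated with r = 0.993 to 0.994 across genes at 1 FPKM or more in both libraries, within cKO with r = 0.985 to 0.991, and between groups with r = 0.930 to 0.952, where genes are not independent replicates. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

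Ets1 itself was not lower in the libraries labelled cKO. Its level was 383, 428 and 391 FPKM in Control 1 to 3 and 467, 445 and 470 FPKM in cKO 1 to 3, with means of 401 ± 23.8 and 461 ± 13.7 FPKM (SD, n = 3 each). The log2 fold change was 0.20 with a standard error of 0.048 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0150), and the values were higher in 3 of 3 cKO libraries. This call was lost without Control replicate 1 (0.17, adjusted p = 0.0505 by limma) and without Control replicate 3 (0.19, adjusted p = 0.0569 by limma), and over all alternatives the adjusted p lay between 0.00678 and 0.0569. The value is one number per gene and can include exons outside the deleted part, which is not given in the sources used here, so it does not check the labels. Every direction below is therefore between the libraries labelled cKO and those labelled Control.

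The libraries labelled cKO had higher levels of genes of interleukin-17-producing helper T cells (Th17), follicular helper T cells (Tfh), effector and memory T cells, chemokine receptors and dividing cells, list calls that were all lost with an estimated correlation (adjusted p = 0.0520 to 0.204). They also had higher levels of markers of plasma cells, B cells, myeloid cells, innate-like lymphocytes and mast cells (adjusted p = 0.0813 to 0.360 with an estimated correlation). Of 87 ribosomal protein genes, 83 were lower. Of 11960 genes kept, 2427 were higher and 2724 lower, together 43.1% (limma with Benjamini-Hochberg adjustment at 0.05). Large changes were mostly rises, with 665 genes higher and 127 lower by a log2 fold change of at least 1. With immunoglobulin, T cell receptor and other-cell markers left out, an alternative chosen after seeing the data, 448 were higher and 129 lower. In 6703 genes (56.0%) all values of one group lay above all values of the other, where chance gives 10%. The first principal component, which separated the groups, held 68.2% of the variance. The median log2 fold change of all kept genes was -0.03.

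**Figure D1:**
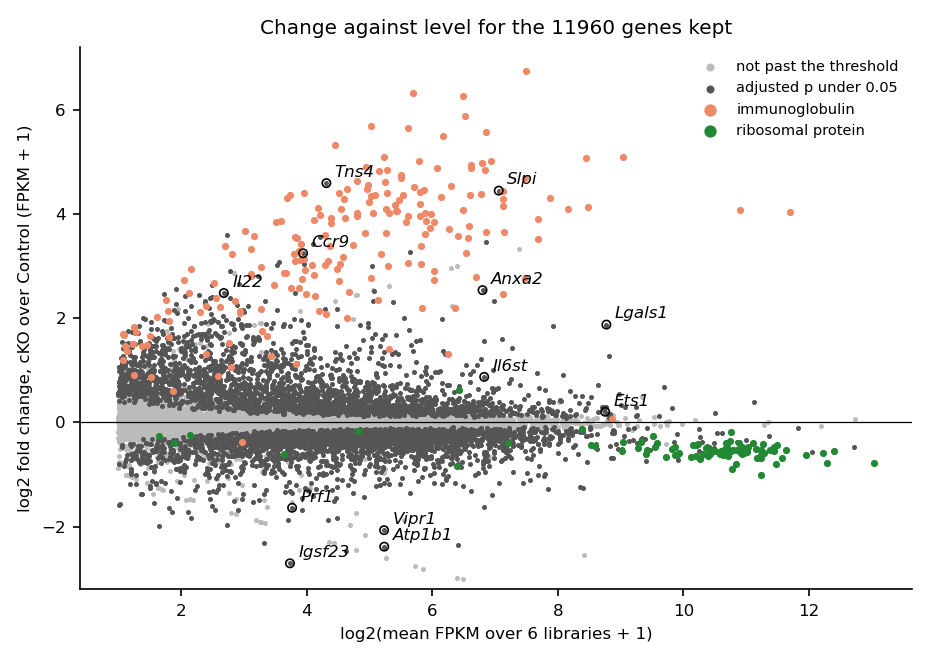
Log2 fold change of libraries labelled cKO over Control, on log2(FPKM + 1), against the log2 mean level over the 6 libraries, 1 point per gene kept. Dark points passed an adjusted p of 0.05 in limma, orange points are immunoglobulin genes, green points are ribosomal protein genes (median -0.54), and circles mark named genes such as Tns4 (4.59) and Igsf23 (-2.71).

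Among the 10 largest rises on log2(FPKM + 1) were a homing receptor and genes known from other immune cells. Which genes rank as largest depends on the pseudocount: of these 10 rises, 4 were among the 10 largest with a pseudocount of 0.1 and 7 with 5, and of the 10 largest falls 6 and 7. Ccr9, a chemokine receptor known for homing to the gut, rose from 1.94 ± 0.174 to 26.8 ± 1.44 FPKM (log2 fold change 3.24). Tns4, which encodes the focal adhesion protein tensin 4, rose from 0.577 ± 0.303 to 37.2 ± 9.31 FPKM (4.59, and 2.90 to 5.88 over all alternatives), and Actg2, a smooth muscle actin, from 2.37 ± 0.238 to 26.7 ± 2.42 FPKM (3.04). Grhl3, a transcription factor of epithelial cells, was listed at 0.0217, 0 and 0.0236 FPKM in Control and stood at 11.3 ± 1.28 FPKM in the libraries labelled cKO. Slpi, a secreted protease inhibitor, rose from 10.2 ± 1.37 to 254 ± 108 FPKM (4.44), Padi4, a peptidylarginine deiminase, by a log2 fold change of 3.07, and Drc1, a component of motile cilia, by 3.43. The plasma cell genes Jchain (3.46) and Mzb1 (3.55) and the neutrophil gene S100a9 (3.26) were also among the 10 largest rises. S100a9 was uneven, at 34.9, 26.4 and 216 FPKM in cKO 1 to 3, and its call was lost without Control replicate 2 (adjusted p = 0.0526 by limma) or 3 (0.0501), with adjusted p between 0.00221 and 0.0526 over all alternatives. In the other 9 rises the adjusted p in limma was at most 9.11e-05. Like S100a9, Slpi (196, 189 and 379 FPKM in cKO 1 to 3), Mzb1, Jchain, Padi4, Tns4 and Grhl3 were highest in cKO 3. Ccr9, Actg2 and Drc1 were highest in cKO 1. The share of immunoglobulin genes was also highest in cKO 3, at 6.90% against 3.33% and 3.70% in cKO 1 and 2. In the same comparison plasma cell markers had a median log2 fold change of 1.59 and myeloid cell markers of 1.52 (adjusted p = 0.236 and 0.360 with an estimated correlation).

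The largest falls included receptors and surface proteins. Igsf23 fell from 22.1 ± 1.58 to 2.53 ± 0.154 FPKM (log2 fold change -2.71), and Atp1b1, a subunit of the sodium-potassium pump, from 62.1 ± 5.58 to 11.2 ± 2.08 FPKM (-2.39). Vipr1, a receptor for vasoactive intestinal peptide, fell from 59.6 ± 1.84 to 13.6 ± 2.46 FPKM (-2.07), and Cd55, which limits complement on the cell surface, from 30.9 ± 1.25 to 7.73 ± 1.34 FPKM (-1.88). Tbxa2r, the thromboxane receptor, fell by 1.69 on the log2 scale. Lypd6b (-2.32), Cnga1 (-1.84), Bambi-ps1 (-1.84), Lbp (-1.73) and Galnt9 (-1.72) completed the 10. Their adjusted p in limma was at most 6.52e-04, and in each of the 10 every cKO library lay below every Control library.

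**Figure D2:**
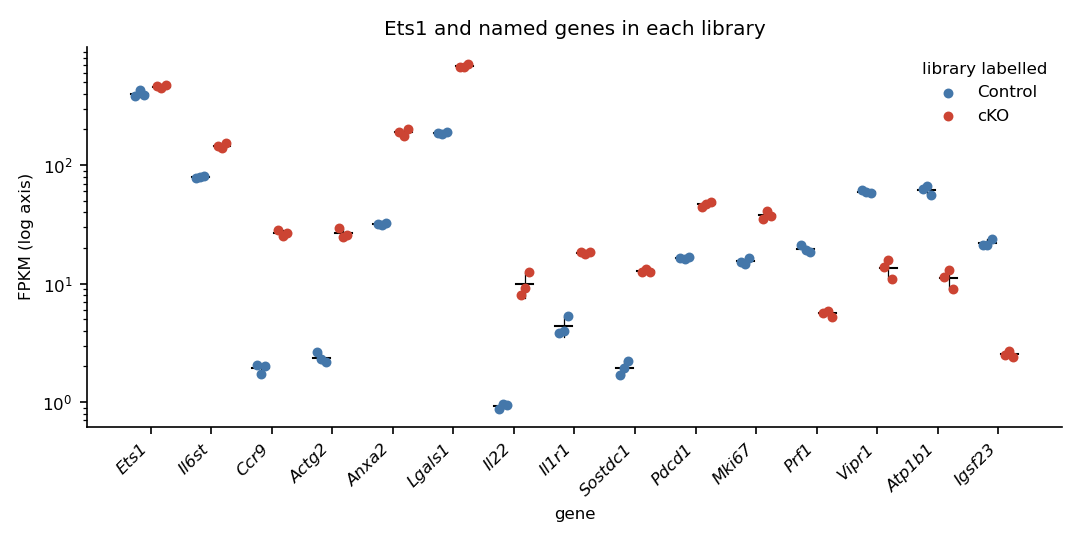
FPKM on a log axis in each library for Ets1, Il6st and 13 genes named by the fixed rule, with 3 Control (blue) and 3 cKO (red) libraries per gene; the line is the mean and the bar 1 SD. Ets1 lies between 383 and 470 FPKM in all 6 libraries, while Ccr9 is at most 2.07 FPKM in Control and at least 25.4 FPKM in cKO.

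Genes of several T cell states were higher in the libraries labelled cKO. Of 17 Th17 genes, 16 rose and 0 fell, with 16 and 0 adjusted over the list alone (median log2 fold change 0.98). Il22, a Th17 cytokine, rose from 0.927 ± 0.0512 to 9.90 ± 2.31 FPKM (2.48, and 1.32 to 3.26 over all alternatives), Il1r1, the interleukin-1 receptor, from 4.38 ± 0.855 to 18.2 ± 0.369 FPKM (1.84), and the chemokine receptor Ccr6 from 21.1 ± 1.38 to 47.6 ± 3.39 FPKM (1.13). Under the filter on mean level, Il22 was kept only because it was higher in cKO, as were Ccr10 and Ier3 in lists below. The shares that rose can thus be partly set by the filter. Il17a (1.06, adjusted p = 0.00607 by limma) was chosen after its values were seen, as was Ccl20, the 1 member that did not pass (-0.37, adjusted p = 0.393 by limma). The list was higher in camera (Benjamini-Hochberg adjusted p = 9.98e-09; adjusted p = 0.167 with an estimated correlation). Of 15 Tfh genes, 12 rose and 1 fell, with 13 and 1 adjusted over the list alone (median 0.70; camera adjusted p = 3.16e-07; adjusted p = 0.204 with an estimated correlation). Pdcd1, which encodes the receptor PD-1, rose from 16.5 ± 0.402 to 46.8 ± 1.96 FPKM (1.45). Sh2d1a, a signalling adaptor needed for help to B cells, rose from 58.3 ± 0.853 to 125 ± 5.84 FPKM (1.09), and Sostdc1 from 1.95 ± 0.255 to 12.8 ± 0.491 FPKM (2.23). Pou2af1 rose too (1.84), and it stands in the plasma cell list as well. The member that fell was Angptl2 (-0.60, chosen after its values were seen). In the same comparison the median was 1.24 for B cell markers, 1.59 for plasma cell markers and 1.25 for segments of the gamma and delta T cell receptor.

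Effector and memory genes and homing receptors moved in the same direction. Of 20 effector and memory genes, 18 rose and 0 fell, also 18 and 0 adjusted over the list alone (median log2 fold change 0.80; camera adjusted p = 2.92e-10; adjusted p = 0.0520 with an estimated correlation). Lgals1, which encodes galectin-1, rose from 186 ± 4.51 to 686 ± 21.4 FPKM (1.87), and Anxa2, a membrane-binding annexin, from 31.8 ± 0.889 to 189 ± 11.8 FPKM (2.54). The integrin gene Itgb1 rose from 56.5 ± 2.19 to 168 ± 5.41 FPKM (1.56) and S100a6 from 105 ± 6.51 to 380 ± 28.8 FPKM (1.84). Prdm1 (0.17) and Cd48 (-0.05), chosen after their values were seen, did not pass. Of 22 chemokine and homing receptor genes, 16 rose and 3 fell, 16 and 3 adjusted over the list alone (median 0.65; camera adjusted p = 6.76e-06; adjusted p = 0.0813 with an estimated correlation). Besides Ccr9, the risers included Ccr2 (1.25) and Ccr6 (1.13). Chosen after their values were seen were Gpr15, a homing receptor of gut and skin (5.74 ± 0.872 to 15.4 ± 0.248 FPKM, 1.29), and Ccr10, a skin-homing receptor (0.926 ± 0.106 to 3.46 ± 0.446 FPKM, 1.21). The fallers, also chosen after their values were seen, were Itga4 (-0.40), Gpr183 (-0.39) and Selplg (-0.21). The median was 1.07 for markers of NK and innate-like lymphocytes and 1.52 for those of myeloid cells.

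Cell cycle genes rose with a single exception. Of 29 members, 28 rose and 0 fell, 28 and 0 adjusted over the list alone (median log2 fold change 1.08; camera adjusted p = 1.80e-13; adjusted p = 0.204 with an estimated correlation). Mki67, a marker of dividing cells, rose from 15.5 ± 1.02 to 37.9 ± 2.77 FPKM (1.24), Top2a, the DNA topoisomerase of dividing cells, from 27.8 ± 2.32 to 73.6 ± 5.59 FPKM (1.37), and Ube2c (1.23) and Cdc20 (1.24) by similar amounts. The replication helicase gene Mcm2, chosen after its values were seen, was the 1 member that did not pass (0.06, adjusted p = 0.390 by limma). The rises differed in size, with a list mean of 0.91, and Pcna, chosen likewise, rose by 0.16 to 0.20 over all alternatives. Plasma cell and myeloid cell markers had medians of 1.59 and 1.52.

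Many genes of regulatory T cells (Treg) rose, while Foxp3, their lineage factor, did not pass. Of 22 members, 15 rose and 2 fell, 15 and 2 adjusted over the list alone (median log2 fold change 0.45; camera adjusted p = 3.23e-05; adjusted p = 0.230 with an estimated correlation). Nt5e, the ecto-enzyme CD73, rose from 25.7 ± 0.662 to 73.5 ± 1.20 FPKM (1.48). Tnfrsf9, the co-stimulatory receptor 4-1BB, rose from 22.6 ± 0.474 to 57.4 ± 3.75 FPKM (1.31), and Tigit, an inhibitory receptor, from 32.0 ± 2.38 to 72.5 ± 1.96 FPKM (1.16). Tgfb1 fell from 73.1 ± 1.45 to 44.4 ± 2.42 FPKM (-0.71). Foxp3, chosen after its values were seen, stood at 50.5 ± 1.27 and 50.3 ± 2.21 FPKM (-0.01, adjusted p = 0.915 by limma). Of 22 T cell activation genes, 13 rose and 3 fell, 14 and 3 adjusted over the list alone (median 0.38; camera adjusted p = 0.00236; adjusted p = 0.204 with an estimated correlation). Xcl1, a lymphocyte chemokine, rose (1.16), while Cd40lg, the ligand with which helper T cells activate B cells, fell from 100.3 ± 0.332 to 64.7 ± 2.63 FPKM (-0.62) and Myc, a growth regulator, from 73.9 ± 0.285 to 46.2 ± 2.97 FPKM (-0.67). Of 12 co-inhibitory receptor genes, 8 rose and 2 fell, 9 and 2 adjusted over the list alone (median 0.61; camera adjusted p = 7.94e-04; adjusted p = 0.236 with an estimated correlation). Cd160 (1.53) and Btla (0.59) rose beside Pdcd1 and Tigit, and the 2 that fell were Vsir (-0.40) and Cd200r1 (-0.39), chosen after their values were seen. The call of Vsir was lost without Control replicate 2 (-0.38, adjusted p = 0.0505 by limma, 5.75e-04 to 0.0505 over all alternatives). Dendritic cell markers had a median of 0.92 and B cell markers of 1.24.

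Il6st, which encodes the shared interleukin-6 family receptor chain gp130, rose from 79.2 ± 1.78 to 146 ± 7.57 FPKM (log2 fold change 0.87, standard error 0.0455, limma adjusted p = 4.32e-05), higher in 3 of 3 cKO libraries. The wider interleukin-6 list did not pass, with 6 of 13 members higher and 2 lower, 6 and 2 adjusted over the list alone (median 0.21; camera adjusted p = 0.0912). It passed with no filter (adjusted p = 0.0477), at a mean of at least 5 FPKM (0.0425) with quantile normalization (0.0210) and in fry (0.0118), within 0.0118 to 0.527 over all alternatives. Socs3, a feedback inhibitor of this pathway, rose (0.42), Jak2 rose (0.29) and Il27ra fell (-0.34). Of 15 common gamma chain receptor and STAT5 genes, 6 rose and 4 fell, 6 and 4 adjusted over the list alone, with a median of -0.02, a mean of 0.04 and an upward direction in camera (adjusted p = 0.505). Il7r, the interleukin-7 receptor of resting T cells, fell from 206 ± 34.2 to 105 ± 10.4 FPKM (-0.96), and Il2rb rose from 98.5 ± 0.895 to 149 ± 4.77 FPKM (0.59). Il21r (0.31) and Bcl2, a survival gene (0.43), also rose.

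The lists for the other helper lineages were mixed. Of 18 Th1 genes, 9 rose and 5 fell, 9 and 5 adjusted over the list alone (median log2 fold change 0.29; camera adjusted p = 0.0751, 0.0453 with quantile normalization and 0.00185 in fry, within 0.00185 to 0.322 over all alternatives). The chemokine gene Ccl5 rose from 67.7 ± 10.4 to 206 ± 14.1 FPKM (1.60) and Nkg7, a cytotoxic granule gene, from 26.1 ± 4.69 to 78.4 ± 6.24 FPKM (1.56). Eomes rose from 2.98 ± 0.0936 to 8.64 ± 0.756 FPKM (1.27) and Il18r1 by 0.98. Ifng (-0.01, adjusted p = 0.984 by limma) and Tbx21 (0.24, adjusted p = 0.155 by limma), chosen after their values were seen, did not pass. Of 13 Th2 genes kept, 8 rose and 3 fell, 8 and 3 adjusted over the list alone (median 0.49; camera adjusted p = 0.105, 0.0186 at a mean of at least 5 FPKM and 0.00216 in fry, within 0.00216 to 0.322 over all alternatives). Nfil3 (0.96), Maf (0.85) and the interleukin-33 receptor gene Il1rl1 (0.69) rose, and Epas1 fell from 4.42 ± 0.0197 to 1.45 ± 0.282 FPKM (-1.15). Gata3, the Th2 lineage factor (-0.05, adjusted p = 0.522 by limma), was chosen after its values were seen. So was Il4, the Th2 cytokine, at 4.96 ± 0.981 and 8.44 ± 2.18 FPKM (0.65, adjusted p = 0.0405 by limma). Its call was lost in 7 settings, among them those without Control replicate 1 (0.64) or 2 (0.54) and without cKO replicate 1 (0.55) or 3 (0.54), with adjusted p between 0.00955 and 0.130 over all alternatives. Of 17 cytotoxic effector genes, 8 rose and 3 fell, 8 and 4 adjusted over the list alone (median 0.36; camera adjusted p = 0.0888). The list passed among genes with a mean of at least 5 FPKM (median 1.26, adjusted p = 0.0339) and in fry (0.0122), within 0.0122 to 0.497 over all alternatives. Its median was 0.05 with quantile normalization, 0.12 with a pseudocount of 5 and 0.64 with 0.1, 0.18 without cKO replicate 3 and 0.56 without Control replicate 1. Prf1, which encodes perforin, fell from 19.6 ± 1.30 to 5.62 ± 0.321 FPKM (-1.64), opposite to Klrk1 (1.26), Ccl5 and Nkg7. NK and innate-like markers, which share Eomes with both the Th1 and the cytotoxic list, had a median of 1.07.

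The naive T cell, T cell receptor and metabolic lists did not pass camera. Of 22 naive T cell genes, 8 rose and 8 fell, 8 and 8 adjusted over the list alone (median log2 fold change 0.03; camera adjusted p = 0.352). Ms4a4b (0.68) and Nsg2 (0.62) rose and Actn1, an actin crosslinker, fell (-0.72). Of 22 T cell receptor signalling genes, 6 rose and 8 fell, 6 and 11 adjusted over the list alone (median -0.09; camera adjusted p = 0.505). Plcg1, a phospholipase below the receptor, fell from 172 ± 2.23 to 117 ± 1.36 FPKM (-0.55), Vav1 from 105 ± 0.418 to 75.2 ± 2.53 FPKM (-0.48). The kinase gene Fyn fell too (-0.34), while Rasgrp1, a Ras activator, rose from 95.3 ± 4.84 to 151 ± 3.74 FPKM (0.66). Of 17 glycolysis genes, 7 rose and 5 fell, 7 and 5 adjusted over the list alone (median 0.07; camera adjusted p = 0.320). Tpi1 (0.87) and Hif1a (0.62) were higher and the glucose transporter gene Slc2a3 (-0.74) and Eno1 (-0.49) lower. Of 20 cholesterol synthesis genes, 2 rose and 4 fell, 1 and 3 adjusted over the list alone (median -0.05; camera adjusted p = 0.505). Sqle (-0.47) was among those that fell. Idi1 was called higher (0.50), a call lost in 5 settings, among them those without Control replicate 2 (0.41) and without cKO replicate 1 (0.43) or 2 (0.48), with limma adjusted p between 0.0170 and 0.154 over all alternatives.

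Single members of the remaining lists changed in both directions. Of 16 Ets family genes, 7 rose and 2 fell, 8 and 2 adjusted over the list alone (median log2 fold change 0.15; camera adjusted p = 0.0300; adjusted p = 0.260 with an estimated correlation). The list lost its call without cKO replicate 1 (adjusted p = 0.0731 in camera), at a mean of at least 5 FPKM (0.117) and with other-cell markers left out (0.0654), within 0.00124 to 0.260 over all alternatives. Etv6 (0.88), Etv5 (1.29) and Spib (1.20) rose and Etv3 fell (-0.57), and Spib is also a B cell marker. Spi1, chosen after its values were seen, was higher by 0.92 to 2.15 over all alternatives. The targeted gene Ets1 (0.20) is itself among the 7 members that rose. Of 24 interferon-stimulated genes, 6 rose and 4 fell, 7 and 4 adjusted over the list alone (median 0.09; camera adjusted p = 0.475). Mx1, an antiviral GTPase, rose from 5.44 ± 0.816 to 16.6 ± 5.57 FPKM (1.40) and Oas2 fell from 23.9 ± 2.51 to 8.46 ± 1.63 FPKM (-1.41), with Ifit2 (-0.82) lower. This list passed camera as higher without cKO replicate 1 (median 0.20, adjusted p = 0.0119, 0.0119 to 0.900 over all alternatives). Of 14 immediate early and stress genes, which can respond to the handling of cells, 2 rose and 7 fell, 5 and 8 adjusted over the list alone. The list had a median of -0.23, a mean of 0.02 and a downward direction in camera (adjusted p = 0.465). Ier3 rose from 0.536 ± 0.128 to 8.72 ± 2.20 FPKM (2.64, and 1.30 to 3.78 over all alternatives), and Jund (-0.68), Dnajb1 (-0.46) and Btg2 (-0.39) fell.

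**Figure D3:**
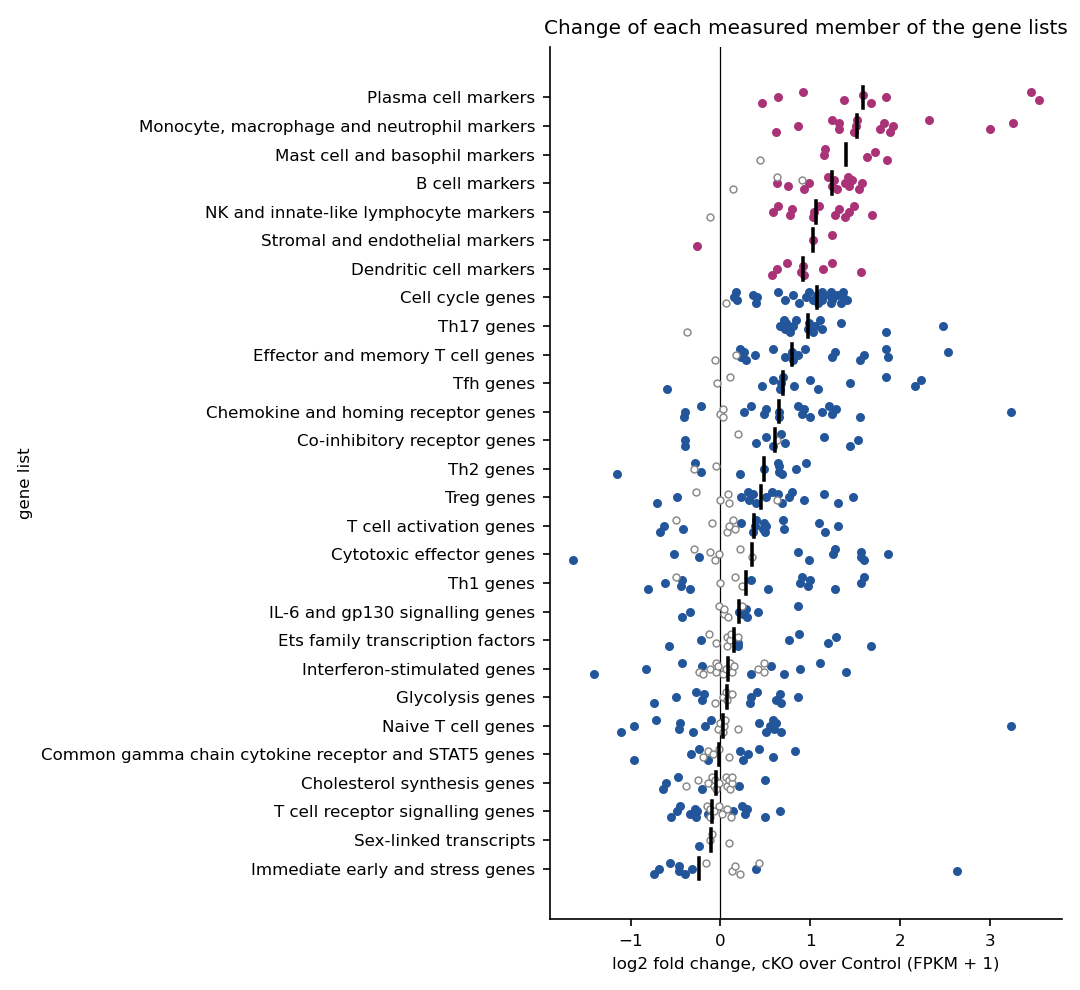
Log2 fold change of libraries labelled cKO over Control, on log2(FPKM + 1), for each measured member of the 28 lists with at least 3 kept members, 1 point per gene and a bar at the median. Filled points passed an adjusted p of 0.05 in limma and open points did not; lists of other cell types (purple) with at least 6 members have medians from 0.92 to 1.59, which a pseudocount of 5 lowers to between 0.36 and 0.98, and cell cycle genes a median of 1.08, lowered to 0.78.

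Markers of cells other than CD4 T cells were higher in the libraries labelled cKO. Genes were kept on the mean over all 6 libraries. A marker under 1 FPKM in Control, such as Cd209a (0.541 against 2.68 FPKM in cKO), was therefore kept only because it was higher in cKO. The shares of kept markers that rose are thus partly set by the filter. All 9 plasma cell markers kept rose (9 of 9 adjusted over the list alone; median log2 fold change 1.59; camera adjusted p = 2.91e-06; adjusted p = 0.236 with an estimated correlation). Jchain, the immunoglobulin joining chain, was at 162, 174 and 299 FPKM in cKO 1 to 3 against 17.6 ± 1.29 FPKM in Control, and Sdc1 was 1.38 higher on the log2 scale. All 15 myeloid markers kept rose (15 of 15 adjusted over the list alone; median 1.52; camera adjusted p = 2.91e-06; adjusted p = 0.360 with an estimated correlation), among them Csf1r (1.92), Mpeg1 (1.90), Tyrobp (1.82) and Itgam (1.78). Their mean level, on log2(FPKM + 1), was 3.76, 4.01 and 4.90 in cKO 1 to 3 against 2.75, 2.32 and 2.42 in Control 1 to 3, and without cKO replicate 3 the median was 1.32. Of 17 B cell markers, 14 rose and 0 fell, 16 and 0 adjusted over the list alone (median 1.24; camera adjusted p = 2.91e-06; adjusted p = 0.322 with an estimated correlation). Pax5, the B cell lineage factor, rose from 0.730 ± 0.260 to 3.09 ± 0.581 FPKM, and Blk (1.39) and Blnk (1.42) rose too. All 9 dendritic cell markers kept rose (9 of 9 adjusted over the list alone; median 0.92; camera adjusted p = 2.33e-04; adjusted p = 0.236 with an estimated correlation), among them Cd86 (1.56), Cd209a (1.25), Ciita (0.93) and Ccl22 (0.58). Of 6 mast cell and basophil markers, 5 rose and 0 fell, also 5 and 0 adjusted over the list alone (median 1.40; camera adjusted p = 0.00343; adjusted p = 0.236 with an estimated correlation). Cpa3 (1.86), Mcpt4 (1.72), Cma1 (1.63) and Fcer1a (1.17) rose.

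Of 14 NK and innate-like lymphocyte markers, 13 rose and 0 fell, 13 and 0 adjusted over the list alone (median log2 fold change 1.07; camera adjusted p = 9.63e-07; adjusted p = 0.0813 with an estimated correlation). Klrb1c, which encodes NK1.1, rose from 3.21 ± 0.242 to 7.67 ± 0.0685 FPKM (1.04) and Klre1 from 1.30 ± 0.0574 to 6.51 ± 1.40 FPKM (1.69). Of the 2 CD8 T cell markers, Cd8b1 rose from 12.7 ± 1.03 to 22.3 ± 1.79 FPKM (0.76), 1 of 2 also adjusted over the list alone. Cd8a, chosen after its values were seen, did not pass (0.42, adjusted p = 0.126 by limma), except without Control replicate 1 (0.59, adjusted p = 0.0434, 0.0434 to 0.487 over all alternatives). Of 3 stromal and endothelial markers, Cxcl13 (1.25) and Ccl21a (1.03) rose and Pecam1 fell (-0.26), the same 2 and 1 adjusted over the list alone (camera adjusted p = 0.465). Of the 2 keratinocyte markers kept, Dsp rose from 0.130 ± 0.0579 to 2.19 ± 0.376 FPKM (1.49). Krt10, chosen after its values were seen, did not pass (-0.62), except adjusted over the list alone and in 5 alternatives, among them that without cKO replicate 1 (-0.81, adjusted p = 0.0201, 0.0201 to 0.146 over all alternatives). Of 6 erythroid markers found, 0 were kept. Of 4 sex-linked transcripts kept, 0 rose and 1 fell, also 0 and 1 adjusted over the list alone (camera adjusted p = 0.475). This was the Y-linked Ddx3y (-0.24), whose call was lost without Control replicate 2 (-0.22, adjusted p = 0.0546 by limma, 0.00484 to 0.0546 over all alternatives). Cd4, chosen after its values were seen, fell from 381 ± 2.29 to a mean of 316 FPKM, at most 323 in a cKO library (-0.27). Cd3e, chosen likewise, did not pass (-0.11, adjusted p = 0.0519 by limma), except without Control replicate 2 or cKO replicate 1 (-0.13 in both, adjusted p 0.0475 to 0.209 over all alternatives).

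**Figure D4:**
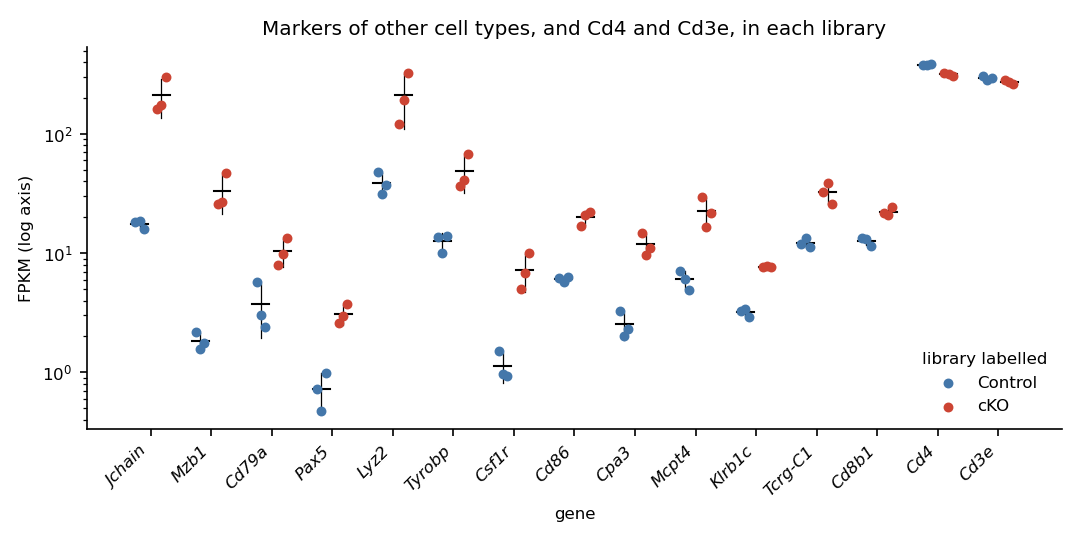
FPKM on a log axis in each library for markers of plasma cells, B cells, myeloid cells, dendritic cells, mast cells, innate-like lymphocytes and CD8 T cells, and for Cd4 and Cd3e, with 3 Control (blue) and 3 cKO (red) libraries per gene; the line is the mean and the bar 1 SD. Jchain is at most 18.4 FPKM in Control and at least 162 FPKM in cKO, while Cd4 stays between 306 and 383 FPKM.

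By camera, 15 of the 28 lists tested were higher and 0 lower in the libraries labelled cKO, and with an estimated correlation 0 were called in either direction (5 higher and 0 lower at an unadjusted p under 0.05). The estimate was -0.020 for the effector and memory list and -0.038 for the chemokine receptor list, below the preset 0.01. A higher correlation therefore does not account for the calls lost in those lists. With an estimated correlation, camera also takes its p from the 4 residual degrees of freedom rather than from the number of genes. This raises p at any correlation, so a call lost there need not reflect correlated members. By fry, a test within each list that does not compare it with other genes, 22 lists were higher and 0 lower (2 lower at an unadjusted p under 0.05). The 7 called by fry and not by camera were the Th1, Th2, naive, interleukin-6, common gamma chain, cytotoxic and glycolysis lists. With immunoglobulin, T cell receptor and other-cell marker genes left out, an alternative chosen after seeing the data, 4970 genes were called (2218 higher, 2752 lower) and 8 lists were higher: the Th17, Tfh, Treg, effector and memory, activation, co-inhibitory, chemokine receptor and cell cycle lists. Leaving out marker genes does not remove other transcripts from the same cells. It therefore cannot tell whether other cells contribute to the rise of these 8 lists.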

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

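The alternatives with length correction, GC correction and other-cell markers left out were chosen after seeing the data. Over the alternatives that keep the threshold alone, 4047 to 5426 genes were called, with 4047 to 4618 when 1 library was left out. No called gene took the opposite direction to its call, except 6 genes under quantile normalization, which also lowered the share of higher genes among those called from 47.1% to 38.1%. That share was 53.3% with no filter, 52.4% with length correction and 53.7% with GC correction, so which direction has more genes depends on the setting. Sizes depend on the pseudocount: of 116 genes named by the rule that passed, 9 log2 fold changes moved by over 1.5 times with a pseudocount of 0.1 and 38 with 5. Counts at a log2 fold change of at least 1 moved more than counts of called genes. Against 665 genes higher, 396 were higher at a mean of at least 5 FPKM and 296 with a pseudocount of 5. Against 127 lower, 199 were lower with a pseudocount of 0.1, 56 with a pseudocount of 5 and 200 with quantile normalization. With that fold change required, 792 of the 5151 genes were left. Against 15 gene lists higher, 8 were higher with immunoglobulin, T cell receptor and other-cell markers left out, where the 6 other-cell lists have no members left and the Ets family list was lost, and 0 with an estimated correlation in camera. Fewer genes tested or a required fold change account for the drop where genes were left out or that limit was added. A larger pseudocount shrinks log2 fold changes and a smaller one widens them, which moves those counts by construction. With an estimated correlation, camera also uses the 4 residual degrees of freedom, which raises p. Elsewhere the cause was not tested.

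With the replicate number as a block (replicate block), 2142 genes were higher and 2322 lower, of which 2081 and 2241 were among those called without it. Deviations from the group mean in libraries of the same number did not go together (r = -0.0074, -0.013 and 0.0080 across genes, which are not independent replicates). Between libraries of different numbers r lay between -0.038 and 0.046. With 3 libraries per group these values are weak evidence on pairing, and the labels do not say that the numbers pair animals. Apart from the estimated correlation, the 14 lists other than the Ets family list kept an adjusted p of at most 0.0117 in camera or fry in every alternative that left members to test. Of the values of named genes under alternatives, 24 lost and 9 gained a call, and none of the named genes, lists or classes changed direction past its threshold. A count test was not run, since FPKM do not give whole reads. Absolute depth is unknown, which limits what can be said of genes listed near 0.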

Other observations

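The gene classes and the tests of transcript length, GC content, immunoglobulin share, other-cell markers and Ets1 were chosen after the result they concern was seen, and the splits of the libraries before.

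Of 192 immunoglobulin genes kept, 166 rose and 0 fell by limma with Benjamini-Hochberg adjustment (173 higher and 0 lower adjusted over the class alone), with a median of 3.55 on log2(FPKM + 1). Genes near 0 in Control could be kept only where cKO was high, so these shares are partly set by the filter. Ighg1, the constant region of IgG1, rose from 201 ± 19.9 to 3613 ± 1633 FPKM (4.07), Ighg2b from 27.0 ± 0.424 to 1019 ± 483 FPKM (5.09) and Ighe, that of IgE, from 2.60 ± 1.95 to 73.1 ± 39.8 FPKM (4.39). Igha rose by 1.41 and Ighd, the constant region of IgD, by 1.12 on the log2 scale. Ighm, the constant region of IgM, stood at a mean of 455 and 477 FPKM (0.06, adjusted p = 0.696 by limma). Igkc, the kappa light chain, was at 4290 FPKM or more in each cKO library and at most 379 FPKM in Control.

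Of 87 ribosomal protein genes kept, 83 fell and 1, Rps27l, rose (0.62), with a median log2 fold change of -0.54, or -0.18 with quantile normalization (62 lower, 3 higher). Rps27 fell from 10618 ± 134 to 6203 ± 202 FPKM (-0.78) and Rpl12 from 3236 ± 63.7 to 1598 ± 27.8 FPKM (-1.02). Ltb, which encodes lymphotoxin beta (-1.24), the T cell surface gene Thy1 (-0.75) and Cd52 (-0.60) fell as well, while other abundant genes such as Ms4a4b (0.68) rose. Of 13 mitochondrially encoded genes, 4 rose and 1 fell.

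Of 92 alpha and beta T cell receptor segments kept, 2 rose, 22 fell and 68 did not pass (median -0.18), with 1 and 19 adjusted over the class alone. Of 12 gamma and delta segments, 9 rose and 0 fell (median 1.25), also 9 and 0 adjusted over the class alone. Tcrg-C1, a gamma constant region, rose from 12.2 ± 1.10 to 32.3 ± 6.31 FPKM (1.32) and Trdc, the delta constant region, from 8.23 ± 1.16 to 17.8 ± 0.526 FPKM (1.03). Of the gamma and delta segments, 3 (Tcrg-C1, Tcrg-C2 and Trdc) also stand in the innate-like lymphocyte list.

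Markers of other cell types were higher in the libraries labelled cKO (adjusted p = 0.0813 to 0.360 in camera with an estimated correlation). In means per library on log2(FPKM + 1), immunoglobulin variable segments rose by at least 2.94 between any Control and any cKO library. The B cell, innate-like, myeloid, dendritic and mast cell lists rose by at most 2.58. The gap was 0.35, or 0.2004 with a pseudocount of 5 and 0.78 with 0.1. The plasma cell list, left out of this test, had a mean rise of 1.73, the same as the myeloid list (1.73). A level in T cells, or a level near 0, damps a log2 rise, and such levels can differ between the sets. The gap therefore cannot decide whether a lower share of CD4 T cells raised every other type alike. For the plasma cell and immunoglobulin genes alone, plasma cells or their RNA among the purified cells are a candidate source. Of 180 variable segments kept, 155 rose and 0 fell (unadjusted p = 0.0513 in camera with an estimated correlation). These genes are themselves part of the pattern, and the filter on mean level favours rises of genes near 0 in Control. A common rise of all these types, from a lower share of CD4 T cells, stays open. Of the 9 plasma cell markers kept, 1 (Pou2af1) is also a Tfh gene, and which cells the negative selection removes is not given in the sources used here. Whether more such cells were present in the nodes or more passed the purification was not tested.

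The median log2 fold change of ribosomal protein genes minus that of genes matched on transcript length and level was -0.4254 (95% of 1000 draws between -0.50 and -0.34). Against genes matched on GC content and level it was -0.3635 (-0.48 to -0.29), but the matched genes were less abundant, with median levels of 9.97 and 9.74 against 10.7 on log2(FPKM + 1). With trends in length or GC content removed from every library, the ribosomal median was still -0.54 or -0.50. This argues against either bias as the whole cause, as far as these lengths and GC contents describe the transcripts. They are those of the longest transcript per symbol, with a median length of 906 for ribosomal protein genes. A bias limited to shorter expressed transcripts was not tested. Immunoglobulin transcripts taking up fragments is argued against as well, since 836 other genes above 100 FPKM in Control had a median log2 fold change of -0.101 (-0.12 to -0.08). A bias that depends on level stays open, since the matched genes were less abundant. Quantile normalization left a median of -0.18, but it makes the distributions of the libraries alike. It can therefore shrink a fall of the most abundant genes whatever its cause, and does not decide this. A biological difference that follows the group and a change in the mixture of cells stay open as well. Neither was tested, and each may account for the fall.

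Ets1 was not lower in the libraries labelled cKO, with a ratio of means of 1.15. Fragments from exons outside the deleted part could keep the gene-level value up, and without values per exon this cannot be told apart from kept expression. Swapped group labels cannot be told apart either: the ratio of Control over cKO was 0.8698, but a gene-level value need not show the loss in either group.

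The 6 libraries can be split into 3 and 3 in 10 ways, and 1 split, the real one, gave 5151 genes, with at most 2 in the others. The splits are too few for a share under 0.05.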
